A study of Mus musculus with 8 samples.

How the data were processed

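Poly(A)-selected RNA was sequenced from cardiac ventricle of mice, 4 samples of heterozygotes for a deletion in Pkp2 and 4 samples of wild-type mice. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a stranded TruSeq poly(A) kit, and the tissue was a mix of left and right ventricle taken at 8 weeks of age. Group membership was taken from the genotype given for each sample, and replicates were numbered within each group in the order of deposition, so the numbers pair nothing. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, and these may share a litter or a day. The sample titles hold digits of which the first 4 are shared by some samples. The labels do not say what they mark. The series title and design name a deletion, the genotype label gives its position without that word, and the name of the deposited table gives a deletion of another base; the title was followed.

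The values are deposited read counts per gene, whole numbers that were not normalised, for 38293 Ensembl genes in each of 8 columns. Per the submitters' processing notes, STAR 2.4.2a and HTSeq 0.6.1 were used with the mouse build GRCm38/mm10. The gene annotation release and the strand setting of the counting were not given in the sources used here. Genes that overlap on opposite strands and genes with near-identical copies are therefore uncertain, since their reads may have been split, shared or dropped. No column of the table lacked a sample. Gene symbols were matched by Ensembl identifier, which gave a symbol for 36345 genes, and the 1948 genes without a symbol held 0.143% of the counts. Positions, exons and gene types came from GENCODE release M21 for GRCm38, the build named in the processing notes.

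Total counts per sample were 32397302 to 41234883. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes of low count were removed with filterByExpr on the groups, which left 14567 genes, and library sizes were scaled by the trimmed mean of M values (TMM). The groups were compared with edgeR's quasi-likelihood test (robust fit, no covariate) with Benjamini-Hochberg adjustment over the genes tested, at an adjusted p of 0.05. Log2 fold changes are heterozygous over wild type, standard errors were derived from the test's F statistic, and intervals are 95% intervals from the same fit. Levels are CPM as computed by edgeR on TMM-scaled library sizes, given as mean ± SD over samples. The common coefficient of biological variation was 0.143. Over genes with at least 100 counts in a pair of samples of a group, the mean chi-square per gene was 14.0 or more in every pair. Sampling noise alone gives about 1, so within a group no library was a re-sequencing of another. Pairs across the groups were not checked, and the value does not show that samples came from separate animals.

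Gene lists (39 lists, 771 genes, of which 3 had no match in the table) covered cardiac junctions, excitation, contraction, stress, matrix, protein turnover, metabolism and markers of cell types that ventricle could hold. Lists with at least 3 tested members, 38 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move, on balance, in a direction or, in its mixed form, in either direction. A list score per library is the mean over members of log2 CPM minus the gene's mean over all libraries. Single values were compared with exact permutation tests over all splits 4 against 4, two-sided, which can give no p below 0.0286.

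The gene lists, tests, first alternatives and wording of the rule for named genes were fixed before the data were examined. The lists to which the rule applied were not, so the set of named genes was not fixed beforehand: the 19 lists described by their members were picked after the list results were seen, partly so that fewer sign changes under the alternatives had to be printed, and the other 20 are given by their medians and tests. The named genes are Pkp2 and every tested member of the desmosome list; then up to 15 higher and 15 lower genes of largest change among those that passed the test and whose groups did not overlap; then, where these are fewer than 20, the genes of smallest p up to 20, sex-linked and predicted genes left out of both steps; in each list described by its members, those past the threshold over the list alone, at most 4, or otherwise the 2 members of smallest p; and 5 sex-linked genes. Genes named outside this rule are said to be chosen after their values were seen.

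The alternatives were RLE, upper-quartile and library-size scaling; no filter, and a filter of at least 1 CPM in at least 4 samples; DESeq2 1.42.0; limma-voom with sample weights; a surrogate variable from sva 3.50.0 as covariate; the title digits as covariate; each sample left out in turn; an adjusted p of 0.10; a test against a fold of 1.2 (glmTreat); and the other list tests. Camera with an estimated correlation within each alternative fit by edgeR and limma-voom was added after the data were seen. Sex as a covariate was not fitted because only a single kind of sample was present. The procedure was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed in each of 5 runs, and 7.21% of the calls made there were genes that had not been changed. Figures were drawn with matplotlib 3.10.9.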

Results

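Ventricular transcriptomes of 4 mouse samples heterozygous for the Pkp2 deletion (HET) were compared with those of 4 wild-type samples (WT), all taken at 8 weeks of age. Pkp2 encodes plakophilin-2, an armadillo-repeat protein of the desmosome, the junction that couples neighbouring heart muscle cells mechanically, and PKP2 is the gene most often mutated in inherited arrhythmogenic cardiomyopathy. The series title places the comparison in the question of how desmosomal proteins are lost in that disease. Total counts were 32397302 to 38611008 in the 4 HET libraries and 38510257 to 41234883 in the 4 WT libraries, with p = 0.0571 for the lower HET mean by an exact two-sided permutation test. In all 8 libraries the Y-linked genes Ddx3y (1379 to 2124 counts), Uty (499 to 673), Kdm5d (509 to 702) and Eif2s3y (1821 to 2382) were present and Xist had 0 to 3 counts.

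The mutated gene itself was lower in every HET library. Pkp2 (ENSMUSG00000041957; chromosome 16, 16213318 to 16272712, plus strand, GRCm38) stood at 99.2, 88.2, 96.0 and 105.6 CPM (counts scaled to library size) in the 4 HET libraries and at 169.1, 167.6, 148.5 and 165.7 CPM in the 4 WT libraries. The means were 97.3 ± 7.2 and 162.7 ± 9.6 CPM (SD, n = 4 each), so HET held 59.8% of the WT level (95% interval 54.1% to 66.1%). The log2 fold change was -0.74 (SE 0.065), with an adjusted p of 0.00376 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The exact two-sided permutation test gave p = 0.0286, the smallest it can give. Coding position 1755 lies at 16262606 on chromosome 16, in exon 9 of 13 (16262565 to 16262738), in codon 585 of a protein of 795 residues. The series title gives the deletion at that position, while the genotype label gives the position without the word deletion and the name of the deposited table gives a deletion of another base. On the reference sequence and with the title's reading, loss of that base shifts the frame into a stop at codon 596, in exon 9, which leaves 4 exons after it and lies 533 bases before the last exon junction.

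**Figure D1:**
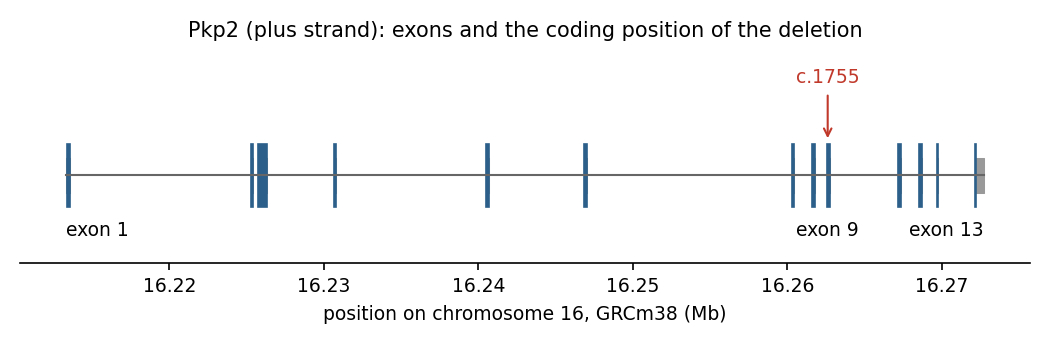
Exons of Pkp2 along chromosome 16 (GRCm38, position in Mb), with coding parts as tall blue blocks and untranslated parts as low grey blocks; the arrow marks coding position 1755. The position lies in exon 9 of 13.

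Of the 7 desmosome genes tested, Pkp2 fell and the other 6 did not pass the test. Dsp (desmoplakin, the link to intermediate filaments) was at 1253 ± 36 CPM in HET and 1257 ± 49 CPM in WT, with a log2 fold change of -0.00 (95% interval -0.10 to 0.09). Jup (plakoglobin) had a log2 fold change of 0.01 (interval -0.14 to 0.16). The desmosomal cadherins Dsg2 and Dsc2 had 0.06 (interval -0.12 to 0.25) and 0.08 (interval -0.03 to 0.18). Pkp4 had 0.07 (interval -0.05 to 0.18), with 0.03 without HET replicate 4 and 0.04 without WT replicate 3, and Perp 0.03 (interval -0.16 to 0.21). The signs of Dsp, Jup and Perp, all near 0, changed under other settings, among them the fit without WT replicate 3 (0.02, -0.01 and -0.00), and the value of Dsg2 moved to 0.00 without HET replicate 3 or WT replicate 1, to 0.10 without HET replicate 1 and to 0.12 without WT replicate 2. Over all genes 1 of the 7 was called, and 1 adjusted over the list alone, Pkp2 in both cases. As a list the desmosome genes were not called (median log2 fold change 0.03, mean -0.07, camera direction down, adjusted p = 0.912 by limma camera and adjusted p = 0.966 with an estimated correlation), while the mixed form of fry, which asks for change in either direction, gave an adjusted p of 7.75e-05. The list holds Pkp2 itself, and fry was not run without it. That value is thus no sign of change in the other 6, whose unadjusted p-values by edgeR were 0.133 (Dsc2) to 0.927 (Dsp).

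**Figure D2:**
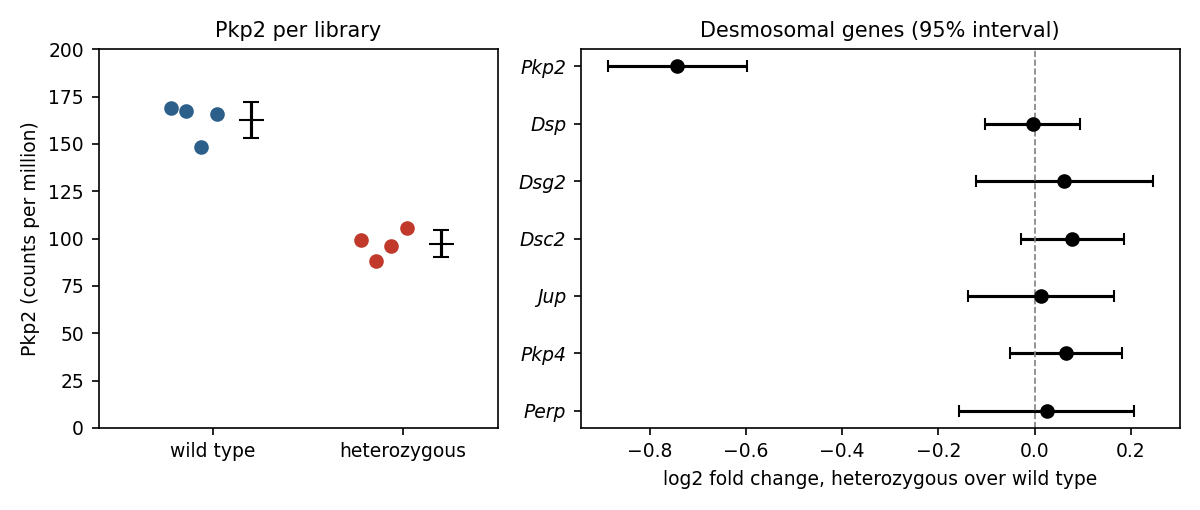
Left, Pkp2 in CPM for each library (points; WT blue, HET red) with the group mean ± SD beside them. Right, log2 fold change (HET over WT) of the tested desmosome genes with 95% intervals; Pkp2 lies at -0.74 and the intervals of the other 6 genes include 0.

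Across the transcriptome Pkp2 was the single gene called by edgeR. Its quasi-likelihood test called 0 genes higher and 1 lower among 14567, against 401 higher and 529 lower at an unadjusted p under 0.05, 930 in all where 728 would arise by chance. DESeq2 called 7 higher and 7 lower (485 and 518 at unadjusted p), and limma-voom 0 higher and 1 lower (561 and 615). The groups did not overlap for 551 genes, 3.78% of those tested, where chance gives 2.86%. In the simulated data 2.8% of genes changed by 1.2-fold were called. The shares were 53.2% for genes changed by 1.5-fold and 75.2% for those changed by 2-fold. At 10 CPM or more they were 3.95%, 83.3% and 95.4% for the same folds. Each simulated run held 200 changed genes, and the adjustment over genes is less strict when many change. These shares may thus be too high for the real data, where 1 gene passed, and do not exclude changes of these sizes.

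The next smallest p belonged to Plk2, a polo-like kinase, at 33.7 ± 2.4 CPM in HET and 47.1 ± 2.9 in WT (log2 fold change -0.48, SE 0.065, adjusted p = 0.114 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It passed without the filter on low counts (adjusted p = 0.0146), without HET replicate 3, where 3 genes passed (Plk2, Pkp2 and Hrasls, which was chosen after its values were seen), and with DESeq2 (2.69e-06). The other 18 genes of smallest p, none of which passed, had adjusted p-values of 0.770 by the same test. Those with the higher mean in HET included Fmo2, a flavin monooxygenase (log2 fold change 0.37, SE 0.068), Clec16a (0.41, SE 0.087), Ttc17 (0.26, SE 0.056), Atp2a2, the calcium pump of the sarcoplasmic reticulum (0.20, SE 0.048), and Dhrs7c, a reductase of the sarcoplasmic reticulum (0.19, SE 0.045). Those with the higher mean in WT included genes of cell division, Tacc3 (-0.76, SE 0.167), Stil (-1.47, SE 0.341) and Mcm5 (-0.60, SE 0.138), the endothelial genes Ramp2 (-0.23, SE 0.051) and Icam2 (-0.27, SE 0.061), and the Notch target Hes1 (-0.56, SE 0.116). The remaining ones were the histone gene H3f3b (-0.27, SE 0.051), the carbonic anhydrase Car7 (-0.51, at 6.25 ± 0.44 CPM in HET and 8.92 ± 0.95 in WT), Gpr183 (-0.97, SE 0.217), St6galnac4 (-0.33, SE 0.073), Vsig10l (-0.50, SE 0.112) and the platelet chemokine Pf4 (-0.35, SE 0.083). Fmo2, Clec16a, Dhrs7c, Hes1, H3f3b, Car7 and Tacc3 passed with DESeq2, and of these Clec16a and Hes1 lie within 20 Mb of Pkp2 on chromosome 16.

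Genes of excitation, calcium cycling and the intercalated disc lay slightly higher in HET as lists, though 0 members passed over all genes. Of 23 ion channel genes of the action potential 19 had a positive log2 fold change (median 0.08), with Kcna5, a potassium channel, at 28.9 ± 3.2 and 21.9 ± 3.1 CPM and Cacna1c, the L-type calcium channel, at 298 ± 24 and 261 ± 16 CPM in HET and WT. Of 18 calcium handling genes 13 were positive (median 0.10), and Atp2a2, at 16279 ± 837 and 14143 ± 423 CPM, was the 1 member called adjusted over the list alone. Of 22 genes of the intercalated disc 17 were positive (median 0.04), with the gap junction gene Gja1 at 0.21 (SE 0.057) and the cadherin Cdh2 at 0.19 (SE 0.078). Adjusted over the list alone, 0 ion channel, intercalated disc and sarcomere genes were called. By limma camera with the preset correlation the adjusted p-values were 7.70e-04 for ion channels, 0.00273 for calcium handling and 0.0482 for the intercalated disc. With an estimated correlation the adjusted p-values were 0.633, 0.633 and 0.941, so none of these calls held, nor did any other list call. The ion channel median was 0.0550 without HET replicate 3. The call for calcium handling ended with the title digits as covariate (median 0.0246, adjusted p = 0.157 by limma camera). That for the intercalated disc ended without HET replicates 1 (0.141), 3 (0.0749) or 4 (0.156) or WT replicates 2 (0.122) or 4 (0.255). The intercalated disc median was 0.0732 without HET replicate 2, 0.0279 without HET replicate 4, 0.0870 without WT replicate 1 and 0.0198 without WT replicate 4. Over all alternatives the adjusted p-values ran from 1.23e-04 to 0.633, 2.44e-04 to 0.633 and 0.00217 to 0.941. The sarcomere list (14 of 21 positive, median 0.02; Myh6 0.12, SE 0.040; Nexn 0.17, SE 0.055) was not called (adjusted p = 0.167 by limma camera), except without HET replicate 2 (0.0418) or WT replicate 2 (0.0256).

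Cell cycle genes were lower in HET as a list. Of 23 members 22 had a negative log2 fold change (median -0.53), none was called over all genes and 3 were called adjusted over the list alone: Mcm5 of the replicative helicase, the mitotic regulator Cdc20 (-0.83, SE 0.229) and the cyclin Ccna2 (-0.73, SE 0.208). These genes were weakly expressed, Cdc20 at 1.11 ± 0.29 CPM in HET and 1.99 ± 0.46 in WT. The list scores of the 4 HET libraries (-0.39 to -0.07) lay below those of the 4 WT libraries (-0.01 to 0.70), with p = 0.0286 by an exact permutation test and 0.557 after adjustment over the 39 lists. Scores did not overlap for 2 lists, this and the desmosome, where chance gives 1.11. The desmosome list holds Pkp2 itself, so its separation says nothing of its other members. By limma camera the adjusted p was 8.14e-08, and adjusted p = 0.633 with an estimated correlation. WT replicate 3 had the highest score, and without it the median was -0.27 (adjusted p = 6.78e-05 with the preset correlation; 5.46e-10 to 0.633 over the alternatives).

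The interferon response list was lower in HET, and WT replicate 3 stood apart from the other 7 libraries on it. All 24 members had a negative log2 fold change (median -0.77, adjusted p = 1.82e-05 by limma camera and adjusted p = 0.941 with an estimated correlation), none was called over all genes and 0 were called adjusted over the list alone. Mx1, an antiviral GTPase, was at 0.56 ± 0.30 CPM in HET and 1.36 ± 1.03 in WT, and Oas1a at 2.58 ± 0.49 and 3.84 ± 1.73, and without WT replicate 3 their log2 fold changes were -0.60 and -0.22 (from -1.29 and -0.58). The list score was 1.64 in WT replicate 3 and -0.66 to -0.03 in the other 7 libraries. Without WT replicate 3 the median was -0.10 and the list was not called (adjusted p = 0.0801; 4.86e-08 to 0.941 over the alternatives), nor was it with a surrogate variable as covariate (median -0.09, adjusted p = 0.0975). That library also had the highest macrophage (0.51) and lymphocyte (0.53) scores and the lowest share of mitochondrially encoded counts, 14.7% against 17.1% to 19.1%, and the first principal component, with 24.9% of the variance, set it apart from the other 7.

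Heat shock and chaperone genes were higher in HET as a list (16 of 20 positive, median 0.11, adjusted p = 0.00204 by limma camera; adjusted p = 0.809 with an estimated correlation). Chordc1, a co-chaperone, had 0.26 (SE 0.105), and Hspa1b, inducible Hsp70, was at 5.17 ± 4.94 CPM in HET and 1.70 ± 0.71 in WT. HET replicate 3 held 12.3 CPM of Hspa1b and the other HET libraries 1.68 to 4.61, and the log2 fold change of 1.61 was 0.72 without it. No member passed over all genes or adjusted over the list alone. WT replicate 3 had the highest score of the WT libraries (0.13 against -0.22 to -0.18), and without it the median was 0.16 (adjusted p = 6.78e-05). The call ended with the title digits as covariate (0.157), and the alternatives ran from 6.78e-05 to 0.809. Of 57 cytosolic ribosomal protein genes 51 were negative, by little (median -0.03; Rps28 -0.16, SE 0.061; Rpl3 -0.18, SE 0.077, and -0.09 without WT replicate 4), with an adjusted p of 0.0422 by limma camera and adjusted p = 0.948 with an estimated correlation. That call ended without HET replicates 3 (0.377) or 4 (0.116) or WT replicates 2 (0.478), 3 (0.160) or 4 (0.116), and the alternatives ran from 1.3e-05 to 0.948. The ribosomal median was -0.0148 without HET replicate 3, -0.0617 without WT replicate 1 and -0.0161 without WT replicate 2. With the title digits as covariate the medians of the ribosomal and intercalated disc lists changed sign (0.01 and -0.00), as did that of the intercalated disc with library-size scaling (-0.00).

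**Figure D3:**
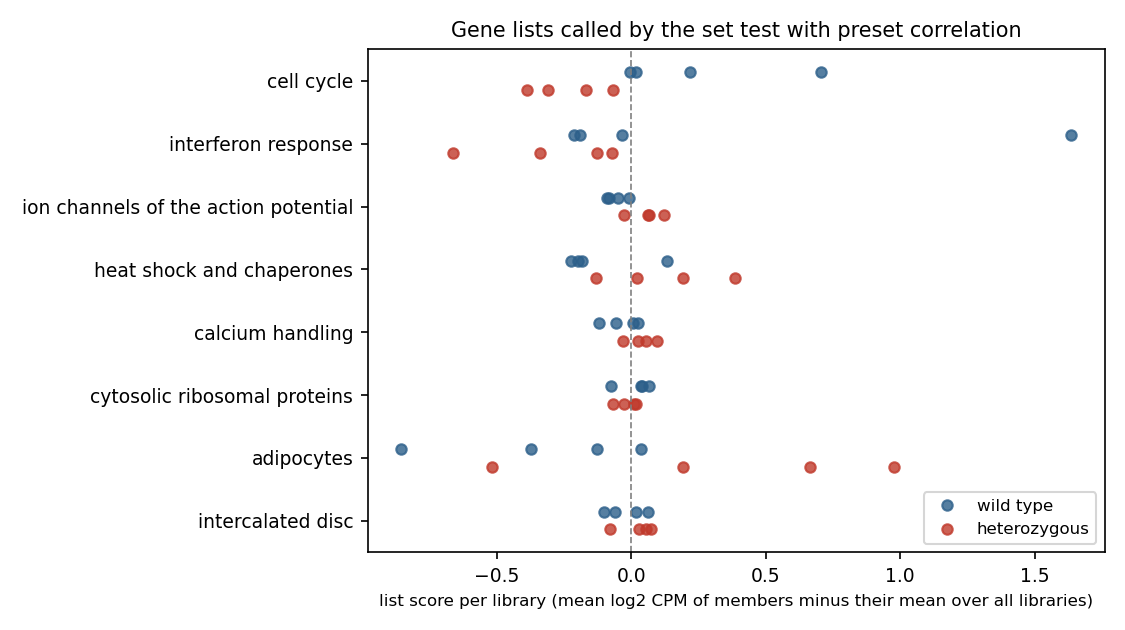
List score of each library (mean log2 CPM of the members minus their mean over all libraries; WT blue, HET red) for the 8 lists called by limma camera with the preset correlation. WT replicate 3 stands at 1.64 on the interferon list, and the cell cycle scores of the groups do not overlap.

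Programmes linked with cardiomyopathy gave no call in the comparison of all 8 libraries without a covariate. Cardiac stress and fetal genes had a median log2 fold change of -0.09 (7 of 17 positive; Mt2 -0.78, SE 0.493; Ccn2 0.24, SE 0.171; adjusted p = 0.775 by limma camera). Without WT replicate 4, which held 51.7 CPM of it, Mt2 had -0.18, and without HET replicate 4 Ccn2 had 0.05. The fetal myosin Myh7, chosen after its values were seen, was at 61.4 to 1093 CPM across libraries of both groups. Extracellular matrix and fibrosis genes had a median of -0.06 and a mean of -0.00 (10 of 32 positive; Tgfb2 -0.28, SE 0.117; Sparc -0.16, SE 0.072; adjusted p = 0.442). Inflammatory cytokines and adhesion molecules had a median of -0.05 (7 of 20 positive; Tlr2 -0.34, SE 0.115; Lif -0.51, SE 0.207; adjusted p = 0.515). With the title digits as covariate the stress list (median -0.20, adjusted p = 0.0125) and the matrix list (-0.17, adjusted p = 3.44e-04) were called lower by limma camera, the latter also without HET replicate 1 (-0.14, adjusted p = 0.0123). With an estimated correlation in the same fits, added after the data were seen, the adjusted p-values were 0.737, 0.737 and 0.819, so these calls rest on the preset correlation. In each of these lists 0 members were called over all genes and 0 adjusted over the list alone.

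Lists of protein and RNA turnover were not called in the comparison of all 8 libraries without a covariate. The proteasome list had a median of 0.00, a mean of -0.00 and the camera direction up (16 of 32 positive; Psma5 -0.11, SE 0.068, and -0.06 without WT replicate 2; Psmb4 -0.07, SE 0.047; adjusted p = 0.968 by limma camera). Ubiquitin ligases and autophagy genes of muscle had a median of 0.05 (19 of 27 positive; Asb2 0.17, SE 0.055; Cbl -0.89, SE 0.327, and -0.49 without WT replicate 3; adjusted p = 0.0589, and called without HET replicate 1 or WT replicate 2 and by limma-voom, at 0.0216 to 0.0412), and nonsense-mediated decay factors 0.02 (10 of 15 positive; Smg5 0.09, SE 0.057, and 0.05 without HET replicate 3; Upf1 0.06, SE 0.051, and 0.03 without WT replicate 4; adjusted p = 0.322). No member of these lists was called over all genes or adjusted over the list alone.

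Adipocyte markers were higher in HET as a list, at very low levels and with a call that was lost in 10 of 19 alternatives. Of 7 adipocyte markers 6 were positive (median 1.01, adjusted p = 0.0482 by limma camera; adjusted p = 0.681 with an estimated correlation), with Cidec, a lipid droplet protein, at 0.57 ± 0.46 CPM in HET and 0.14 ± 0.09 in WT and the adipokine Adipoq, which lies within 20 Mb of Pkp2, at 0.42 ± 0.29 and 0.14 ± 0.09. No adipocyte marker was called over all genes or adjusted over the list alone. The list scores overlapped, with HET replicate 4 at -0.52 and WT replicate 4 at 0.04. The call ended without HET replicate 3 (median 0.51, adjusted p = 0.0749), WT replicate 1 (0.124) or WT replicate 2 (0.107) and with a filter of 1 CPM (median 0.03, adjusted p = 0.714), and the alternatives ran from 8.55e-04 to 0.714. Among 13 adipogenic regulators 9 were positive (median 0.07, adjusted p = 0.217) and 1 was called adjusted over the list alone, Cebpd, a transcription factor, at 17.7 ± 4.1 CPM in HET and 11.3 ± 1.1 in WT (log2 fold change 0.64, SE 0.151). Cebpd did not pass over all genes with edgeR and passed with DESeq2 (adjusted p = 0.0384), and it too lies within 20 Mb of Pkp2. Its start lies at -0.326 Mb from that of Pkp2, against 6.93 Mb for Adipoq.

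Of 10 Wnt targets 4 were positive (median -0.03, adjusted p = 0.811 by limma camera), and Ccnd1, cyclin D1, was the 1 member called adjusted over the list alone, at 66.3 ± 6.1 CPM in HET and 80.4 ± 6.3 in WT. Of 14 endothelial markers 7 were positive (median 0.00, mean -0.01, camera direction up, adjusted p = 0.930), and Egfl7 was the 1 called adjusted over the list alone, at 117 ± 11 and 144 ± 10 CPM. Over all genes neither Ccnd1 nor Egfl7 passed (adjusted p = 0.770 for each by edgeR's quasi-likelihood test). Calls adjusted over a list alone, here and for other lists, were not adjusted for the number of lists. In the comparison of all 8 libraries without a covariate the other tested lists gave no call, and 0 members were called over all genes or adjusted over the list alone. By limma camera these were the unfolded protein and integrated stress response (median 0.04, mean -0.01, adjusted p = 0.570), nuclear-encoded oxidative phosphorylation (0.01, adjusted p = 0.217), fatty acid oxidation (0.03, mean -0.01, adjusted p = 0.0889), glycolysis (0.04, adjusted p = 0.0589) and YAP and TAZ targets (-0.05, adjusted p = 0.811). Circadian clock genes (median -0.17, mean -0.26) had the camera direction up (adjusted p = 0.930) and the highest score in WT replicate 2 (0.56), immediate early genes a median of -0.16 (adjusted p = 0.381) and mitochondrially encoded mRNAs 0.07 (adjusted p = 0.190). Oxidative phosphorylation was called higher with the title digits (median 0.07, adjusted p = 1.58e-09) and without HET replicate 3 (0.0119), WT replicate 2 (5.13e-06) or WT replicate 4 (0.0290). Fatty acid oxidation was called higher with the title digits (0.08, adjusted p = 3.75e-04) and without HET replicate 1 (0.0334), WT replicate 2 (0.0326) or WT replicate 4 (0.00320), and glycolysis without HET replicate 2 (0.0418) or WT replicate 4 (0.0290). The unfolded protein response was called higher with the surrogate variable (0.0138) or without WT replicate 3 (0.0149), and clock genes with the title digits (0.0386). Immediate early genes were called lower without HET replicate 3 (2.79e-04) or WT replicate 1 (0.0277), and mitochondrially encoded mRNAs higher without WT replicate 2 (0.0256). All calls that lists gained under an alternative rest on the preset correlation. With an estimated correlation in the same fits 0 of the 37 held, at adjusted p-values of 0.455 to 0.953 by limma camera (0.737 for oxidative phosphorylation with the title digits).

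Apart from adipocytes, markers of other cells gave no call by limma camera with all 8 libraries and no covariate. The medians were -0.13 for macrophages (adjusted p = 0.0666) and -0.25 for lymphocytes (adjusted p = 0.0807), lists on which WT replicate 3 was the highest library (0.51 and 0.53). Macrophages were called lower with the title digits (adjusted p = 0.0436) and without HET replicate 1 (0.0392), HET replicate 4 (0.0296), WT replicate 1 (0.0202), WT replicate 2 (0.00570) or WT replicate 4 (0.0403), and lymphocytes without HET replicate 2 (0.0418), WT replicate 1 (0.0277) or WT replicate 4 (0.0421). The medians were 0.25 for neutrophils (adjusted p = 0.268, and 0.0160 without a filter or 0.0105 without WT replicate 4), 0.05 for erythroid cells (adjusted p = 0.431, and 0.0193 with the surrogate variable or 0.0178 without WT replicate 3), 0.05 for smooth muscle cells and pericytes (adjusted p = 0.721) and -0.01 for fibroblasts (adjusted p = 0.811). Epicardial and mesothelial cells had 0.07 (adjusted p = 0.775), Schwann cells and neurons 0.00 (adjusted p = 0.775), atrial cardiomyocytes -0.11 (adjusted p = 0.570), the conduction system -0.01 (adjusted p = 0.930) and skeletal muscle -0.13 (adjusted p = 0.570). Of the lung markers 1 was expressed enough to be measured.

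Measures of library composition were compared between the groups. The number of genes with a count was 18896 ± 118 in HET and 19216 ± 147 in WT (SD, n = 4 each; exact permutation p = 0.0286, 0.114 after adjustment over 6 measures), in the direction of the lower totals of HET, and its ranges did not overlap. The number did not follow the totals in every library. WT replicate 4 had a lower total than HET replicate 1 (38510257 against 38611008) and more genes with a count (19396 against 18997). The TMM scaling factor was 0.985 ± 0.006 in HET and 1.01 ± 0.02 in WT (exact permutation p = 0.0571, 0.114 after adjustment), and without this scaling 116 genes were higher and 968 lower at an unadjusted p under 0.05, against 401 and 529 with it. The 10 most counted genes took 25.05% ± 0.63 of counts in HET and 24.2% ± 1.8 in WT (exact permutation p = 0.514). Mitochondrially encoded genes took 17.98% ± 0.83 and 17.4% ± 1.9 (exact permutation p = 0.771), and haemoglobin genes 0.0337% ± 0.0039 and 0.0339% ± 0.0120 (exact permutation p = 0.971).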

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

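The tests on the interferon pattern in WT replicate 3 were chosen after it was seen. In a check for a library far from the other 3 of its group, 14 of 204 sets of values stood out, where chance gives about 1 in 20 groups, or 10.2, and 6 of these were in WT replicate 3. The number in parentheses is the gap to the nearest library as a share of the group's range.

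WT replicate 3 was highest on the interferon list (1.64 against -0.21 to -0.03 in WT; 0.904), in Mx1 (2.90 CPM against 0.70 to 0.95; 0.886), in Hspa1b (2.75 CPM against 1.23 to 1.42; 0.878) and on the heat shock list (0.13 against -0.22 to -0.18; 0.887). It was lowest in Fmo2 (22.3 CPM against 26.5 to 27.1; 0.869) and in Pkp2 (148 CPM against 166 to 169; 0.836), where it still lay above every HET library.

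All 24 interferon genes were highest in WT replicate 3, by a median of 1.85 on the log2 scale over the mean of the other 7 libraries, and of genes chosen after their values were seen, Igtp reached 1118 CPM against at most 17.9 and Iigp1 1728 against at most 82.0. A rise of macrophages and lymphocytes in proportion to their markers does not account for all of it. Their 22 markers were higher by a median of 0.581 (SD 0.29), below the interferon median by more than their spread. Some extra immune cells stay open, among them cells with raised interferon genes, since the markers do not measure that. Library scaling is excluded as the cause, since a factor moves all genes of a library alike, while 0.509% of the tested genes outside the list reached the interferon median. This comparison replaced that of the median over all genes, which TMM scaling holds near 0. A variant shared with WT replicate 4, the other library without Ifi202b, that raises these genes by itself is argued against, since the interferon median of WT replicate 4 was 0.0128. That value does not cover a shared variant that acts only together with another difference of WT replicate 3. A response to interferon in that sample may explain the pattern, and no biological explanation was tested, since the labels give no health record and no group for it.

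The other values that stood out follow without explanation. Ttc17 was lowest in HET replicate 2 (41.9 CPM against 46.1 to 46.3; 0.937), Psmb4 highest in HET replicate 1 (121 CPM against 115 to 116; 0.831) and Rpl3 highest in WT replicate 4 (88.4 CPM against 68.7 to 71.5; 0.857). List scores stood out for lymphocytes in HET replicate 2 (0.10 against -0.23 to -0.20; 0.933) and for Schwann cells and neurons in WT replicate 2 (-0.41 against 0.08 to 0.17; 0.835). HET replicate 4 stood out on smooth muscle cells and pericytes (0.05 against 0.00 to 0.01; 0.854), skeletal muscle (-0.38 against 0.05 to 0.07; 0.937) and the single tested lung marker (-0.41 against 0.07 to 0.15; 0.857).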

How the results depend on the processing

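All alternatives were chosen beforehand, except the estimated correlation within other fits, which was added after the data were seen. Pkp2 stayed lower in HET and past the threshold in every other fit, with log2 fold changes of -0.79 to -0.70 when each sample was left out and with glmTreat against a fold of 1.2 (adjusted p = 0.0366, the single gene called there). DESeq2 called 7 genes higher, 7 lower and 5 lists. The count of lower genes was 2 without a filter on low counts (Plk2 and Pkp2) and 1 to 3 when a sample was left out, with 3 without HET replicate 3, and no higher gene was called in those fits by edgeR, where 219 to 597 had a higher mean at an unadjusted p under 0.05 (485 by DESeq2). The number of lists called was 13 at an adjusted p of 0.10, 0 with an estimated correlation (also 0 in each alternative fit by edgeR and limma-voom), 0 with fry and 7 to 12 when a sample was left out, and of the 30 lists without a call 15 were called in at least 1 alternative. For the 56 named genes 1025 of 1054 outcomes kept direction and side of the threshold, 12 passed that had not and 17 turned. Most of these genes come from lists picked after the results were seen, partly to shorten the sign changes to print, so the tally is not independent of them. For the 8 lists 106 of 152 kept both, 44 lost the call and 2 turned in the direction given by camera. Dsp turned to 0.00122 with DESeq2, 0.00968 with limma-voom and 0.0190 with the surrogate variable, and ran from -0.0255 to 0.0177 when a sample was left out. Jup turned to -0.00342 with upper-quartile and -0.0294 with library-size scaling, -0.00837 with the surrogate variable and -0.0635 with the title digits, and ran from -0.0395 to 0.0669 when a sample was left out. Perp turned to -0.0169 with library-size scaling and -0.00628 with the surrogate variable, and ran from -0.0402 to 0.0858 when a sample was left out. With the title digits the median of the intercalated disc list was -0.00368 and that of the ribosomal list 0.0123. With library-size scaling the intercalated disc list lost its call (adjusted p = 0.0815 by limma camera) and its median was -0.000201, with the camera direction unchanged. The cause of these changes was not tested. At an unadjusted p under 0.05, 401 genes were higher and 529 lower, against 262 and 650 with upper-quartile and 116 and 968 with library-size scaling. With the title digits as covariate 1 gene and 10 lists were called, and libraries of different groups that share them had a mean correlation of deviations of -0.01 over 5 pairs, against 0.01 over 11 other pairs. Sex as a covariate was not run, since all 8 libraries held Y-linked transcripts. No paired analysis was possible because the labels number no replicates.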

Other observations

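The tests on the level of Pkp2 and on genes near Pkp2 were chosen after the results were seen. For the genes present in some libraries alone, the thresholds that define them were set after examples were seen, and the bound of the test on linked variants was changed after its result, as was that of the share of genes near Pkp2.

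Myh7, the slow myosin heavy chain, differed widely between libraries of both genotypes. It was at 1055, 1065, 1093 and 975 CPM in HET replicates 2 and 3 and WT replicates 2 and 3, and at 61.4, 83.0, 89.6 and 73.3 CPM in HET replicates 1 and 4 and WT replicates 1 and 4. Myh6, the main ventricular myosin, was at 32744 to 37635 CPM in all 8. The extracellular matrix score was -0.19, -0.21, -0.13 and -0.17 in the former libraries and 0.23, 0.16, 0.19 and 0.11 in the latter, in the same order. Myh7 was chosen after its values were seen, and no groups were compared on it.

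Clock genes set WT replicate 2 apart. Dbp was at 231 CPM there and at 30.2 to 113 CPM in the other 7 libraries, and Per3 at 69.0 against 14.4 to 29.8 CPM. Arntl, which cycles in antiphase to Dbp, was at 3.42 CPM against 12.4 to 28.8. The labels give no time of day, and these genes were chosen after their values were seen.

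Of the 14567 tested genes 26, Myh7 among them, split into libraries of high and of low level, with a gap of at least 3 on the log2 scale and at least 2 libraries on each side, in 17 patterns of which 0 followed genotype; Slc6a16, chosen after its values were seen, had 9.88 to 14.3 CPM in 5 libraries and 0 in HET replicates 1 and 2 and WT replicate 2. For these genes a batch that follows the title digits is argued against, since 0% of the genes had a single state within each block of digits. Variants that segregate between the mice stay open: the bound written beforehand, a permutation p of 0.05 or more, was met with p = 1, but it was set aside afterwards because just 2 pairs of these genes lay within 20 Mb of each other, too few for linked patterns to show. Reads shared with near-identical copies cannot be told apart from variants, since 18 of the genes are pseudogenes and 6 of the 25 with an annotated type, or 24%, are protein coding, between the bounds set for that test. No biological explanation was tested.

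Genes near Pkp2 were tested for a haplotype linked to the mutated allele. Of 255 tested genes within 20 Mb, 7.84% had an unadjusted p under 0.05 by edgeR against 6.34% elsewhere, a share above that of 81.4% of blocks of as many neighbouring genes and thus within the usual range, and 0 passed when adjusted over these genes alone. The 100 genes of smallest p by edgeR held 6 of them, where 1.77 would be expected, so the share does not exclude an effect on a few genes. A test added after that share was seen, once calls on chromosome 16 had been noticed, used the calls of DESeq2: of 13 genes other than Pkp2, 5 lie within 20 Mb, among them Clec16a, Cebpd, Hrasls and Hes1, where 0.230 would be expected and the highest of 43 blocks held 1. Linked strain haplotype around Pkp2 may affect a few genes, a hypothesis found and tested on the same calls, while edgeR called none of the 5 with all 8 libraries and Hrasls without HET replicate 3; the labels give no strain, so an effect of the mutation on these genes stays open.

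Loss of all transcript from the mutated allele with no change of the other would leave 50% of the WT level of Pkp2, and the 95% interval of the ratio had a lower bound of 54.1%. With the other allele unchanged, the mutated allele would give 19.6% of a normal allele's transcript (8.19% to 32.1%). A higher output of the other allele stays open, since counts per gene do not separate the alleles.

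Chance cannot be excluded for the numbers of calls. Of the 35 splits of the 8 libraries, 14 called at least as many genes as the real split, which called 1, and the highest other count was 19 (HET replicates 1, 3 and 4 with WT replicate 3). For lists, 27 of the 35 called at least the 8 of the real split, and the highest other count was 17. A split with 19 genes points to a structure of the samples, and what sets it apart was not tested. The split that follows the title digits (HET replicates 1, 3 and 4 with WT replicate 1) called 3 genes and 11 lists and had 1686 genes at an unadjusted p under 0.05, the highest of the 35 and above the 930 of the real split. The next highest were 1580 (HET replicates 1, 3 and 4 with WT replicate 3) and 1493 (HET replicates 1 and 2 with WT replicates 2 and 4). Both follow the digits in part. The former keeps HET replicates 1, 3 and 4 together, and the latter HET replicates 3 and 4 with WT replicate 1, all of which share their digits. Splits with lower numbers follow the digits in part as well. The real split, with 930 genes, also keeps HET replicates 1, 3 and 4 together. The split of HET replicates 1 and 2 with WT replicates 3 and 4 keeps HET replicates 3 and 4 with WT replicate 1 and had 375. These splits therefore cannot tell whether the number is particular to the digits. With the digits as covariate the comparison of genotypes called 1 gene, Pkp2, and 10 lists. Digits and genotype are partly confounded, since HET replicates 1, 3 and 4 share theirs with WT replicate 1 alone. WT replicate 2 shares its digits with no other library, so it adds nothing to the comparison of genotypes in that fit. That fit therefore does not cleanly separate genotype from the digits.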
